A study of Mus musculus with 16 samples.

How the data were processed

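RNA sequencing libraries of primary brown (interscapular) and white (inguinal) mouse preadipocytes with and without Fgf8b were analysed, 16 libraries in 4 groups of 4, each library with its own number and no number shared between groups. Controls carry odd and Fgf8b libraries even numbers, and no label pairs them. White libraries carry the numbers 1 to 8 and brown libraries 9 to 16, so depot runs with library number. Per the labels, total RNA was extracted with TRIsure and columns and libraries were made with the TruSeq RNA Sample Prep kit v2, and the submitters' processing notes name CASAVA and bcl2fastq without versions. The authors deposited a table of RPKM per transcript, written with decimal commas, with 168326 entries and 16 columns. A range check found 0 values that were not numeric, 0 below 0, a highest value of 9575.12 and 0 columns holding only whole numbers. Whether the libraries are strand-specific and which genome build was used are not given in the sources used here, so antisense partners cannot be told apart and no coordinates are printed. The design text speaks of 3 cultures and which libraries share a culture is not given.

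Values behave as whole reads over transcript length and depth: 95.6 to 96.0% of values of up to 50 reads lay within 0.1 of a whole read, which gave depths of 13.7 to 20.1 M reads. Depth was 15.6 to 19.8 M in white controls, 16.2 to 20.1 M in white Fgf8b, 13.7 to 16.1 M in brown control and 14.6 to 16.0 M in brown Fgf8b libraries. Between libraries of a group the chi-square per degree of freedom of recovered reads was 1.32 to 2.62, and 7.65 to 8.31 for pairs with brown control 15. Of the entries, 23172 (13.8%) carry no gene symbol and were left out, and 299 accessions are repeated on 808 entries. All 808 were left out too, some of which carry no gene symbol either, so the sum of a gene lacks its repeated accessions. Of the repeated accessions, 145 have unequal values in the inguinal libraries and 0 in the brown libraries, so the depots may come from separately made tables.

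The 144549 entries used were summed to 29060 genes by symbol. Genes with at least 0.5 RPKM in at least 4 libraries were kept, which left 15222. Values were taken as log2(RPKM + 0.5) and tested with limma 3.58.1 in R 4.3.3, with a mean-variance trend and robust moderation over all 16 libraries, and genes with a Benjamini-Hochberg adjusted p under 0.05 were called. The comparisons were Fgf8b against control in each depot, brown against white under each treatment, and the difference of the responses, brown minus white. Lists of genes, 28 with 612 entries of which 603 matched the table (8 by a synonym), were written before the data were examined and tested with camera at a preset correlation of 0.01 when at least 5 members were tested, adjusted within a comparison. Their tests were repeated with an estimated correlation and with fry. Counts of members are out of those that passed the filter, which for several lists were fewer than the matched members. Among these lists, 7 of 22 skeletal muscle, 6 of 14 epithelial, 9 of 15 endothelial, 8 of 12 Schwann cell and 5 of 16 leukocyte markers passed. So did 22 of 32 adipocyte differentiation and 20 of 26 thermogenic genes. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 did the rest, and GENCODE release M21 served for shared sequence words of 31 bases and GC content.

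Named genes followed a rule: 8 fixed genes in every comparison, the 3 members of each list that changed most with a mean of at least 1 RPKM, and the 5 largest changes each way among genes with a mean of at least 5 RPKM. The rule gave 201 genes, of which the text names a part. Results for 2 named genes are not reported here. Levels are those of a representative transcript (NM_009463 for Ucp1, NM_011198 for Ptgs2, NM_009573 for Zic1, NM_010462 for Hoxc10, NM_009263 for Spp1).

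The test was tested on simulated data with 7662 genes and a dispersion of 0.001, equal to the floor set for it. For Fgf8b in white preadipocytes it called 35 of 50 genes changed 1.25-fold (70%), 49 of 50 changed 1.5-fold (98%), 50 of 50 changed 2-fold and 49 of 49 changed 4-fold, and 4 of 7463 unchanged genes. False calls among the same 7463 genes were 0 for Fgf8b in brown, 0 between control depots, 8 between depots with Fgf8b and 5 for the difference of the responses. In the real data, pairs with brown control 15 had a chi-square per degree of freedom of 7.65 to 8.31. Other pairs within a group had 1.32 to 2.62. The shares called and the false calls hold for data simulated at a dispersion of 0.001. They may not carry over to these libraries, least of all where brown control 15 is compared. Comparisons and alternatives were chosen before the data were examined, apart from the use of RefSeq transcripts alone. The plan put counts ahead of normalized values. Since the table holds no counts, its branch for normalized values was used, and the planned tests that need counts were not run, apart from voom on recovered reads. Reads were recovered for 12284 genes, of which 7939 passed a minimum of 0.5 CPM in at least 4 libraries and were tested. Other alternatives were other scaling factors, other filters, thresholds and pseudocounts, the groups compared alone, a block of adjacent library numbers, the most abundant transcript and each library left out in turn.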

Results

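The series measured transcript abundance by RNA sequencing in primary mouse preadipocytes, the fibroblast-like precursors of fat cells that grow out of the stromal-vascular fraction of fat tissue. Cells came from interscapular brown fat, a heat-producing depot, or from inguinal white fat, a subcutaneous storage depot, of C57BL/6N mice carrying a Ucp1 reporter. Cultures received Fgf8b, a secreted fibroblast growth factor that signals through FGF receptors and the ERK kinases, or a control treatment. The dose and the time of treatment are not given in the sources used here. There were 16 libraries in 4 groups of 4: white control, white Fgf8b, brown control and brown Fgf8b. Depth read back from the values was 13.7 to 20.1 M reads per library, with a mean of 18.0 M in white controls, 18.2 M in white Fgf8b, 15.4 M in brown control and 15.1 M in brown Fgf8b libraries. Libraries are named by group and by the number in their label. Levels and reads are those of a representative transcript, with RPKM as mean ± SD over n = 4 libraries. It is the RefSeq transcript with the highest mean, or the entry with the highest mean where a gene has no RefSeq transcript. Fold changes are of the sum over a gene's entries, on the log2(summed RPKM + 0.5) scale, with their standard error (SE). This scale understates the change of low genes. The design text speaks of 3 independent cultures while each group has 4 libraries, so p-values measure the spread between these samples, part of which may be technical.

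The white preadipocyte comparison asked which transcripts Fgf8b changed in cells of the inguinal depot. With Fgf8b, feedback genes of FGF signalling, glycolysis genes and cell-cycle genes rose. Matrix genes fell for 28 and preadipocyte markers for 17 of their members while 6 of each rose, calls lost with an estimated correlation (adjusted p = 0.1 and 0.0518). Ucp1, the uncoupling protein of brown fat mitochondria, rose from 2.31 ± 0.257 RPKM to 6.25 ± 0.722 RPKM, resting on 62 to 80 reads per control library and 155 to 224 reads per Fgf8b library. Ptgs2, the inducible cyclooxygenase of prostaglandin synthesis, rose from 4.34 ± 0.193 to 26.2 ± 1.72 RPKM. Spp1, the secreted matrix protein osteopontin, rose from 88.8 ± 4.76 to 8509 ± 264 RPKM, the largest log2 fold change among genes with a mean of at least 5 RPKM (6.58, SE 0.046). Pparg, the master regulator of fat cell differentiation, fell from 4.73 ± 0.103 to 2.13 ± 0.206 RPKM.

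Limma called 10007 of 15222 genes changed by Fgf8b in white preadipocytes, 5521 higher and 4486 lower, and 1779 of these changed at least 2-fold, 668 higher and 1111 lower. The balance of the directions turned with scaling, to 4860 higher and 4979 lower with median-of-ratios factors and 4738 and 5105 with upper-quartile factors. Of the genes fixed for every comparison, Ucp1 changed by 1.37 (log2, SE 0.116, limma adjusted p = 4.89e-09), Ptgs2 by 2.57 (SE 0.090, adjusted p = 1.11e-14) and Prdm16, a transcriptional regulator of brown fat identity, by 0.55 (SE 0.072, adjusted p = 1.97e-06). Pparg fell by 1.06 (SE 0.092, limma adjusted p = 7.94e-09). Ppargc1a, a coactivator of mitochondrial genes, fell by 0.88 in its summed value (SE 0.238, limma adjusted p = 0.00306). Its representative transcript alone had 10 to 22 reads per control library and 0 to 5 reads per Fgf8b library. The reads behind the other entries in the sum are not given. Fgfr1, a receptor of Fgf8b, stood at 74.7 ± 0.945 and 75.8 ± 1.92 RPKM (log2 0.02, limma adjusted p = 0.537). That difference turned its sign with median-of-ratios factors (-0.03) and upper-quartile factors (-0.04). Fgfr2, another FGF receptor, fell from 6.73 ± 0.255 to 1.48 ± 0.0865 RPKM. Of 9 FGF receptors and co-receptors tested, 3 rose and 2 fell (camera adjusted p = 0.763).

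Of 29 FGF and ERK feedback and target genes, 23 rose and 4 fell (camera adjusted p = 2.08e-07, and adjusted p = 0.0211 with an estimated correlation). Dusp6, a phosphatase that inactivates ERK, rose 6.48-fold, Spry4, a feedback inhibitor of receptor signalling, 3.02-fold, and Etv4, an ERK-induced transcription factor, 6.74-fold. Hmga2, a chromatin protein of growing mesenchymal cells, rose from 12.1 ± 0.566 to 150.2 ± 8.68 RPKM, and Areg, a ligand of the EGF receptor, from 0.146 ± 0.0692 to 10.9 ± 2.21 RPKM. Of 35 proliferation genes, 33 rose and 0 fell (camera adjusted p = 5e-12, and adjusted p = 0.0211 with an estimated correlation), among them Ube2c and Ccnb2, which act in mitosis, each 2.15-fold. Of 21 glycolysis genes, 19 rose and 1 fell (camera adjusted p = 2.15e-08, and adjusted p = 0.0211 with an estimated correlation). Slc16a3, a lactate exporter, rose 5.48-fold and Pdk1, which restrains pyruvate oxidation, 3.4-fold. Several members of this list, Gapdh, Pgk1 and Eno1 among them, share most of their sequence with near-identical copies, so their own values are uncertain. Of 17 prostaglandin genes, 13 rose and 3 fell (camera adjusted p = 0.0021, but adjusted p = 0.115 with an estimated correlation). Besides Ptgs2, Ptgs1, the constitutive cyclooxygenase, rose 2.91-fold and Ptges, a prostaglandin E synthase, 2.80-fold. Of 16 hypoxia response genes, 13 rose and 3 fell (camera adjusted p = 0.00111, but adjusted p = 0.0593 with an estimated correlation), with Egln3, an oxygen sensor, 8.31-fold and Bnip3, a mitophagy receptor, 3.99-fold higher. Of 36 nuclear respiratory chain genes, 25 rose and 0 fell, by a median of 0.23 (log2; camera adjusted p = 0.000167, but adjusted p = 0.244 with an estimated correlation). With median-of-ratios or upper-quartile factors 22 rose and 1 fell.

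Of 35 fibrillar and basement membrane matrix genes, 28 fell and 6 rose (camera adjusted p = 1.77e-11, but adjusted p = 0.1 with an estimated correlation). Col14a1, a collagen of fibril surfaces, fell from 31.6 ± 1.52 to 0.351 ± 0.0437 RPKM, Eln, elastin, from 11.7 ± 0.331 to 0.602 ± 0.0744 RPKM and Col12a1 from 54.7 ± 4.21 to 6.70 ± 0.448 RPKM. Outside the list, Fmod, a collagen-binding proteoglycan, and Igfbp3, a binding protein of insulin-like growth factors, were 60.1-fold and 47.7-fold lower. Of 24 preadipocyte and fibroblast markers, 17 fell and 6 rose (camera adjusted p = 0.000222, but adjusted p = 0.0518 with an estimated correlation). F3, tissue factor, fell from 505.9 ± 8.98 to 27.6 ± 1.15 RPKM and Wisp2, a secreted WNT-related protein, from 64.7 ± 5.63 to 2.36 ± 0.412 RPKM. Of 17 smooth muscle and myofibroblast genes, 13 fell and 4 rose (camera adjusted p = 0.000364, but adjusted p = 0.188 with an estimated correlation), and Rgs5, a pericyte gene, was among those that rose, 22.9-fold. All 25 interferon response genes fell (camera adjusted p = 1.25e-08, but adjusted p = 0.289 with an estimated correlation): Ifit3 went from 158.1 ± 20 to 44.7 ± 8.49 RPKM and Mx1, an antiviral GTPase, from 5.43 ± 1.15 to 0.670 ± 0.186 RPKM. Lyz2, a macrophage lysozyme, fell beside them from 1.23 ± 0.164 to 0.0919 ± 0.0523 RPKM, 1 of 5 leukocyte markers tested, of which 2 fell and 1 rose (camera adjusted p = 0.497).

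The other lists were not called in white preadipocytes. Of 20 thermogenic genes 5 rose and 7 fell (camera adjusted p = 0.763). Ucp1 and Cox7a1, a respiratory subunit typical of brown fat, rose, and Acot2, a mitochondrial thioesterase, fell 4.10-fold. Of 22 adipocyte differentiation genes 10 fell and 5 rose (camera adjusted p = 0.138). Lpl, lipoprotein lipase, fell from 162.9 ± 6.73 to 19.7 ± 1.16 RPKM and Klf15, an adipogenic transcription factor, 11.5-fold. Of 23 matrix protease genes 11 rose and 12 fell, with a median of -0.79, a mean of 0.07 and a downward test (camera adjusted p = 0.408). Mmp3, a stromelysin, rose 10.3-fold and Timp3, a protease inhibitor, fell 8.98-fold. Of 19 inflammatory genes 8 rose and 9 fell (camera adjusted p = 0.507). Il33, an alarmin, was 15.7-fold higher and Il1rn, the interleukin-1 receptor antagonist, 30.4-fold lower. Of 21 BMP and TGF-beta response genes 9 rose and 11 fell (camera adjusted p = 0.445), with Id4, a BMP target, 19.5-fold lower and Grem1, a BMP antagonist, 4.56-fold higher. Of 16 WNT response genes 5 rose and 8 fell (camera adjusted p = 0.241), with Sfrp1, a WNT antagonist, 9.57-fold lower. Counts were 3 higher and 6 lower of 13 brown fat lineage genes (camera adjusted p = 0.212), 4 and 8 of 16 white and posterior patterning genes (0.408), 10 and 9 of 25 cholesterol synthesis genes (0.792; 7 and 9 with median-of-ratios factors, 6 and 10 with upper-quartile factors), 9 and 11 of 22 amino acid and integrated stress response genes (0.507) and 0 and 2 of 6 mitochondrially encoded genes (0.507). Among markers of other cell types, 2 of 9 endothelial markers rose and 6 fell (camera adjusted p = 0.0982), 3 of 7 skeletal muscle markers rose and 1 fell (0.763), 2 of 6 epithelial markers rose and 2 fell (0.91), 0 of 8 Schwann cell markers rose and 4 fell (0.133), and 1 of 6 mesothelial markers, Bnc1, rose and 2 fell (0.709). In the cholesterol, epithelial and mesothelial lists the median and the mean had opposite signs, and in the thermogenic list the median was 0.01 while the mean was -0.11. Adjusted over the list alone, all of these counts were equal except for the respiratory chain genes (26 higher).

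**Figure D1:**
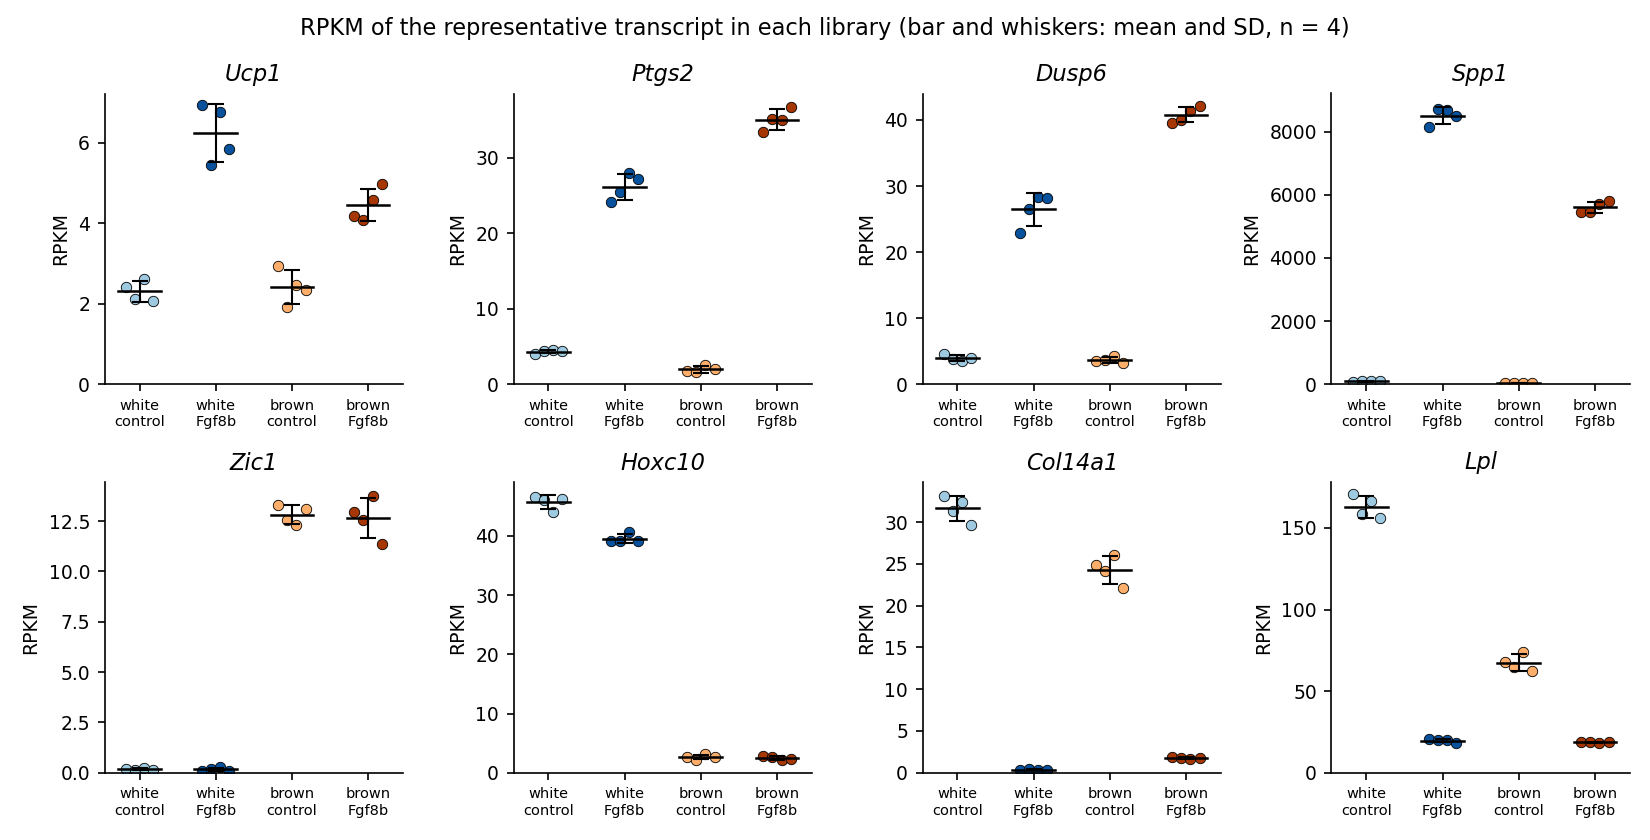
RPKM of the representative transcript of 8 genes (y axes, from 0) in each of the 16 libraries, by group (x axes); points are libraries, bars and whiskers are means and SD of 4 libraries. Ucp1, Ptgs2, Dusp6 and Spp1 were higher with Fgf8b in both depots, Col14a1 and Lpl were lower, and Zic1 and Hoxc10 separated brown from white with either treatment.

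The brown preadipocyte comparison asked the same of cells of the interscapular depot. With Fgf8b, FGF feedback genes and cell-cycle genes rose here too. Most matrix, smooth muscle, cholesterol synthesis and stress response genes fell, but these lists lost their call with an estimated correlation (adjusted p = 0.0731, 0.0878, 0.0731 and 0.221). Ucp1 rose from 2.41 ± 0.419 to 4.45 ± 0.408 RPKM, on 50 to 76 and 101 to 120 reads per library, and Ptgs2 from 1.97 ± 0.422 to 35.0 ± 1.39 RPKM. Spp1 went from 36.2 ± 3.15 to 5601 ± 181 RPKM, and Angptl4, a secreted inhibitor of lipoprotein lipase, from 2.35 ± 0.147 to 160.8 ± 3.88 RPKM. Aspn, a small leucine-rich proteoglycan, fell from 47.4 ± 9.59 to 0.0720 ± 0.068 RPKM.

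Limma called 10864 of 15222 genes changed in brown preadipocytes, 5582 higher and 5282 lower, and 2177 of these changed at least 2-fold, 763 higher and 1414 lower. Here too the balance turned, to 5251 higher and 5586 lower with median-of-ratios factors and 4676 and 6113 with upper-quartile factors. Ucp1 changed by 0.86 (log2, SE 0.116, limma adjusted p = 2.24e-06), Ptgs2 by 4.14 (SE 0.090, adjusted p = 7.87e-18), Prdm16 by 0.39 (SE 0.072, adjusted p = 8.43e-05) and Fgfr1 by 0.39 (SE 0.030, adjusted p = 1.15e-09). Pparg fell by 0.81 (SE 0.092, limma adjusted p = 2.49e-07). Ppargc1a, at 0.115 ± 0.0442 and 0.122 ± 0.0397 RPKM for its representative transcript, did not pass the test on its summed value (log2 0.21, limma adjusted p = 0.437). Brown control 15 stood apart from the other brown controls, and without it 10872 genes were called.

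Of 29 FGF and ERK feedback and target genes, 26 rose and 2 fell (camera adjusted p = 2.58e-12, and adjusted p = 0.00216 with an estimated correlation). Dusp6 rose 10.8-fold, Spry4 6.6-fold, Etv4 11.1-fold, Hmga2 16.6-fold and Areg from 0.0282 ± 0.0327 to 11.5 ± 0.565 RPKM. All 35 proliferation genes rose (camera adjusted p = 7.16e-13, and adjusted p = 0.0207 with an estimated correlation). Ube2c was 2.34-fold and Rrm2, a subunit of ribonucleotide reductase, 2.30-fold higher. Of 21 glycolysis genes 16 rose and 2 fell (camera adjusted p = 6.98e-06, but adjusted p = 0.0585 with an estimated correlation). Slc16a3 was 6.00-fold and Pfkl, a phosphofructokinase, 3.43-fold higher. Of 17 prostaglandin genes 12 rose and 2 fell (camera adjusted p = 0.000546, but adjusted p = 0.0731 with an estimated correlation). Ptges was 4.38-fold and Ptgs1 2.47-fold higher. Of 36 nuclear respiratory chain genes 28 rose and 0 fell, by a median of 0.24 (log2; camera adjusted p = 5.07e-05, but adjusted p = 0.192 with an estimated correlation). With upper-quartile factors 23 rose and 1 fell.

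Of 35 matrix genes 29 fell and 5 rose (camera adjusted p = 8.77e-12, but adjusted p = 0.0731 with an estimated correlation). Eln fell 63.4-fold, Col14a1 13.3-fold and Col12a1 13-fold, and Fmod, outside the list, 43.6-fold. Of 24 preadipocyte markers 18 fell and 3 rose (camera adjusted p = 0.000244, but adjusted p = 0.0585 with an estimated correlation). Wisp2 was 46.3-fold and F3 11.3-fold lower. Of 17 smooth muscle genes 13 fell and 1 rose (camera adjusted p = 2.44e-05, but adjusted p = 0.0878 with an estimated correlation), with Lmod1, a nucleator of smooth muscle actin, 6.45-fold and Cnn1, calponin, 4.63-fold lower. Of 25 cholesterol synthesis genes 19 fell and 1 rose (camera adjusted p = 1.85e-05, but adjusted p = 0.0731 with an estimated correlation). Tm7sf2, a sterol reductase, was 2.80-fold lower. Of 22 amino acid and integrated stress response genes 18 fell and 3 rose (camera adjusted p = 6.98e-06, but adjusted p = 0.221 with an estimated correlation), with Trib3, a pseudokinase induced by stress, 6.84-fold and Vldlr, a lipoprotein receptor, 3.82-fold lower. All 8 Schwann cell markers tested, of 12 in the list, fell (camera adjusted p = 0.0134, but adjusted p = 0.0731 with an estimated correlation), S100b from 8.40 ± 1.26 to 1.29 ± 0.371 RPKM.

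The interferon list was not called in brown preadipocytes: 9 of 25 members fell and 2 rose, 7 and 2 adjusted over the list alone (camera adjusted p = 0.416). Psmb9, an immunoproteasome subunit, fell 2.96-fold and Usp18, a brake on interferon signalling, rose 1.55-fold. The leukocyte markers again held 2 that fell and 1 that rose of 5 tested (camera adjusted p = 0.416), Lyz2 going from 2.96 ± 0.819 to 0.171 ± 0.140 RPKM. Of 16 hypoxia genes 10 rose and 3 fell (camera adjusted p = 0.0858). Of 20 thermogenic genes 8 rose and 8 fell (camera adjusted p = 0.888), and of 22 adipocyte differentiation genes 7 rose and 8 fell (camera adjusted p = 0.39), Lpl 3.54-fold and Klf15 3.70-fold lower. Inflammatory genes were 9 higher and 8 lower of 19 (camera adjusted p = 0.841), with Il1rl1, the receptor of interleukin-33, at 6.97 ± 0.0937 and 269.9 ± 8.52 RPKM and Il11, a cytokine of fibroblasts, 13.4-fold higher. Matrix proteases were 9 higher and 12 lower of 23 (camera adjusted p = 0.343), with a median of -0.67 and a mean of 0.07. Mmp3 rose 25-fold and Adamts5, an aggrecanase, fell 13-fold. BMP and TGF-beta genes were 9 higher and 12 lower of 21 (camera adjusted p = 0.416), with Id4 17.7-fold lower and Ltbp1, a TGF-beta binding protein, 6.05-fold higher. Not called either were the lineage (5 higher, 5 lower of 13), patterning (4, 8 of 16), receptor (3, 4 of 9), mitochondrially encoded (0, 3 of 6), WNT (7, 7 of 16), endothelial (2, 6 of 9), skeletal muscle (1, 4 of 7), epithelial (2, 2 of 6) and mesothelial lists (2, 2 of 6), with camera adjusted p from 0.113 for the endothelial list to 0.987 for the receptor and epithelial lists. Adjusted over the list alone, counts differed only for the lineage (6 lower), matrix protease (13 lower), interferon and WNT (8 lower) lists. The median and mean had opposite signs in the receptor, inflammatory, matrix protease and epithelial lists.

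**Figure D2:**
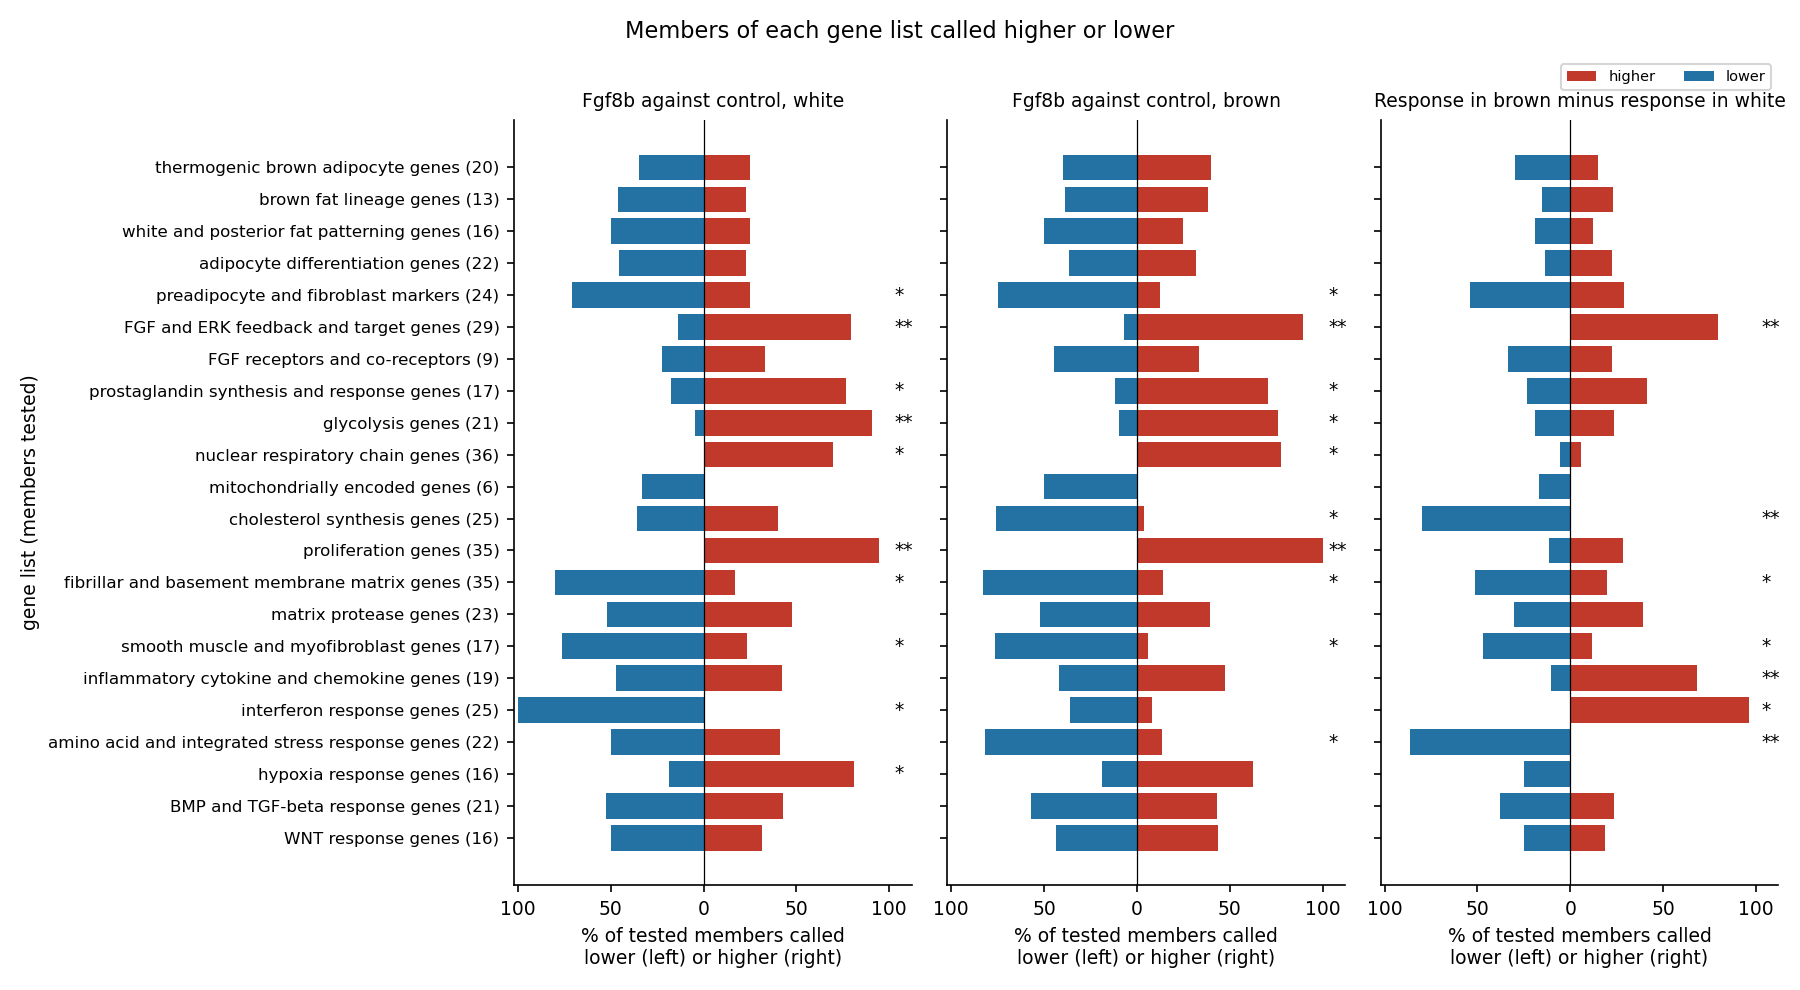
Percent of the tested members of 22 gene lists (y axis, members tested in brackets) called higher (right) or lower (left) by limma with Fgf8b in white and in brown preadipocytes and in the difference of the responses; 1 asterisk marks a list called by camera with the preset correlation and a pair of asterisks one called with an estimated correlation too. All 25 interferon response genes were lower in white preadipocytes, against 9 in brown, and all 35 proliferation genes were higher in brown.

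The difference of the responses, brown minus white, asked whether Fgf8b acted alike in both depots. The responses ran in parallel for most genes, while FGF feedback genes had a higher response in brown cells, and cholesterol and stress response genes responded lower in brown cells. Interferon genes responded lower in white cells, a call lost with an estimated correlation (adjusted p = 0.342). Across all 15222 genes, which are not independent replicates, the log2 fold changes of the depots had a Pearson r of 0.855 and a Spearman rho of 0.799. Both lists held 4342 genes that rose, where independent lists would share 2025, and 3683 genes that fell, where independent lists would share 1557. Genes that rose in white but fell in brown cells numbered 265, and 144 went the other way. These comparisons share no library, but they share the same fit, filter and estimate of spread for each gene. Genes with a small spread can for that reason be called in both more often than in independent lists.

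Limma's interaction test called 5313 genes, 2604 with a higher and 2709 with a lower response in brown cells, and 604 of these differed at least 2-fold. That split moved to 2780 higher and 2533 lower with median-of-ratios factors and 2293 and 3052 with upper-quartile factors. Without brown control 15, 5875 were called. Ptgs2 rose more in brown cells (difference 1.58, SE 0.128, limma adjusted p = 3.76e-08), as did Spry4 (1.13, SE 0.110, adjusted p = 3.49e-07) and Dusp6 (0.74, SE 0.114, adjusted p = 5.95e-05). Fgfr1 had a higher response in brown cells (0.37, SE 0.043, limma adjusted p = 2.78e-06) and had not passed the test in white cells. The rise of Ucp1 was smaller in brown cells (-0.51, SE 0.164, limma adjusted p = 0.021). Ppargc1a differed by 1.10 in its summed value (SE 0.336, limma adjusted p = 0.0165), while its representative transcript alone had very few reads. Pparg (0.25, limma adjusted p = 0.157) and Prdm16 (-0.16, adjusted p = 0.258) did not pass the test.

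Of 29 FGF and ERK genes, 23 had a higher and 0 a lower response in brown cells, 24 and 0 adjusted over the list alone (camera adjusted p = 4.4e-14, and adjusted p = 0.00114 with an estimated correlation). Egr1, an immediate early transcription factor, fell by 1.22 in white cells and rose by 0.74 in brown cells (difference 1.96, SE 0.073), its relative Egr2 differed by 1.82 and Dusp5, a nuclear ERK phosphatase, by 1.94. Of 19 inflammatory genes 13 had a higher and 2 a lower response in brown cells, 14 and 3 adjusted over the list alone (camera adjusted p = 3.26e-06, and adjusted p = 0.0122 with an estimated correlation). Il1rl1 differed by 2.85 and Il11 by 1.69, whereas Il33 differed by -2.29. Of 25 cholesterol genes 0 had a higher and 20 a lower response in brown cells, 21 adjusted over the list alone (camera adjusted p = 8.53e-12, and adjusted p = 0.0122 with an estimated correlation). Hmgcs1, an early enzyme of the pathway, differed by -0.76. Of 22 amino acid and integrated stress response genes 0 had a higher and 19 a lower response, 20 adjusted over the list alone (camera adjusted p = 4.42e-16, and adjusted p = 0.0461 with an estimated correlation). Chac1, a glutathione-degrading enzyme, rose by 0.40 in white cells and changed by -1.54 in brown cells (difference -1.94, SE 0.131), Trib3 differed by -1.70 and Vldlr by -1.59.

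Of 25 interferon response genes 24 had a higher and 0 a lower response in brown cells, with the same counts adjusted over the list alone (camera adjusted p = 1.14e-11, but adjusted p = 0.342 with an estimated correlation). Mx1 differed by 2.57 (SE 0.289, limma adjusted p = 1.84e-06) and Rsad2, an antiviral enzyme, by 1.96 (SE 0.200, adjusted p = 5.72e-07). Of 35 matrix genes 18 had a lower and 7 a higher response in brown cells, 20 and 8 adjusted over the list alone (camera adjusted p = 0.00223, but adjusted p = 0.555 with an estimated correlation). Lum, the proteoglycan lumican, rose in white cells and fell in brown cells (difference -2.92, SE 0.178), while Col14a1 fell less in brown cells (2.46, SE 0.110). Of 17 smooth muscle genes 8 had a lower and 2 a higher response, 10 and 2 adjusted over the list alone (camera adjusted p = 0.00696, but adjusted p = 0.342 with an estimated correlation), with Rgs5 differing by -2.97 and Notch3, a receptor of mural cells, by -1.54. Of 7 skeletal muscle markers 4 had a lower response, 5 adjusted over the list alone (camera adjusted p = 0.0362, but adjusted p = 0.2 with an estimated correlation), and that call was lost without white control 5 or without brown control 15. Outside these lists Angptl4 rose more in brown cells (2.79, SE 0.113), Lpl fell less there (1.23, SE 0.064), and Serpinb1a, a protease inhibitor, and Tgfb2, a TGF-beta ligand, fell more there (-2.32 and -1.79).

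The remaining lists were not called in the difference of the responses. Higher and lower responses in brown cells numbered 3 and 6 of 20 thermogenic, 3 and 2 of 13 lineage, 2 and 3 of 16 patterning, 5 and 3 of 22 differentiation and 7 and 13 of 24 preadipocyte genes. They numbered 2 and 3 of 9 receptor, 7 and 4 of 17 prostaglandin, 5 and 4 of 21 glycolysis, 2 and 2 of 36 respiratory chain and 10 and 4 of 35 proliferation genes. They numbered 9 and 7 of 23 protease, 0 and 4 of 16 hypoxia, 5 and 8 of 21 BMP and TGF-beta and 3 and 4 of 16 WNT genes, and 0 and 3 of 8 Schwann cell markers. They numbered 0 and 1 of 6 mitochondrially encoded genes, 0 and 0 of 5 leukocyte, 1 and 0 of 9 endothelial, 0 and 1 of 6 epithelial and 2 and 1 of 6 mesothelial markers. Adjusted over the list alone they were 3 and 7 for the thermogenic, 0 and 0 for the respiratory chain and mitochondrially encoded, 10 and 5 for the proliferation, 6 and 8 for the BMP and TGF-beta, 4 and 7 for the WNT and 4 and 1 for the mesothelial list. Camera's adjusted p for these lists ran from 0.062 for the hypoxia and Schwann cell lists to 0.893 for the receptor list.

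**Figure D3:**
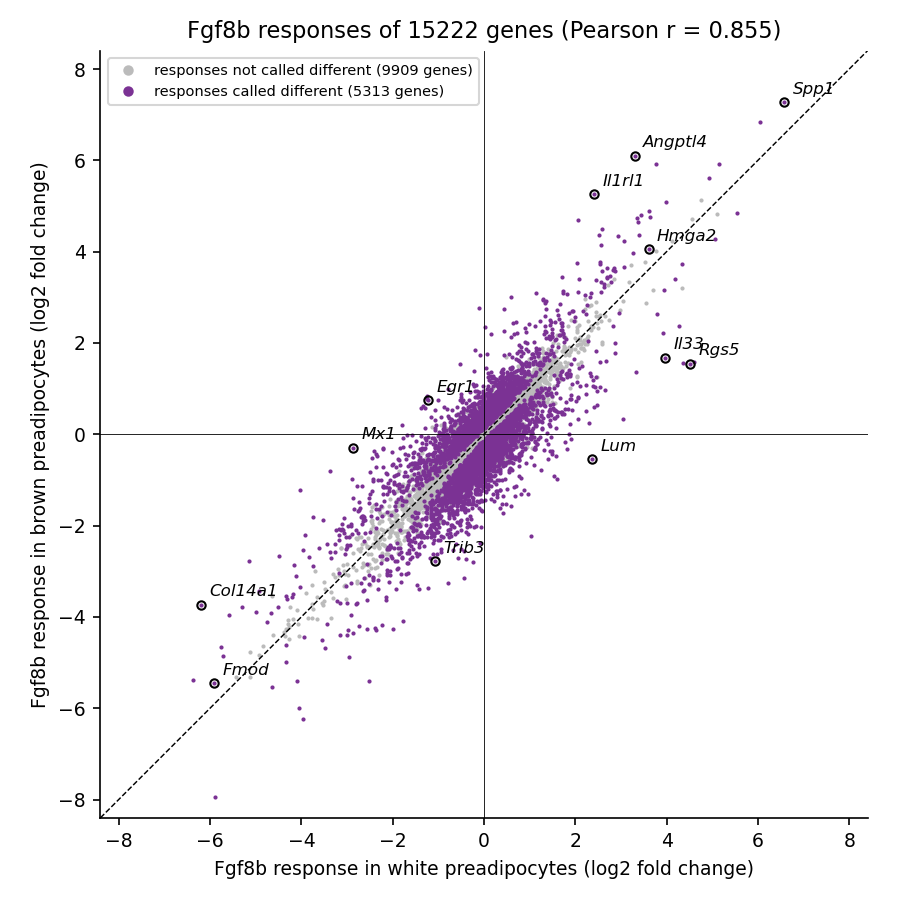
Log2 fold change with Fgf8b in white (x axis) and in brown preadipocytes (y axis) of 15222 genes, 1 point per gene, on the log2(summed RPKM + 0.5) scale; the dashed line marks equal responses, and purple points are genes called different by limma's interaction test. Most genes lie along the line (Pearson r of 0.855), while Il1rl1 and Angptl4 lie above it and Lum, Rgs5 and Trib3 below it.

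The comparison of the depots under control treatment asked how brown and white preadipocytes differed before Fgf8b. Single patterning genes differed widely, though the list of white and posterior patterning genes was not called. Zic1, a marker of brown fat precursors, stood at 12.8 ± 0.468 RPKM in brown and 0.176 ± 0.0497 RPKM in white controls, and Hoxc10, a posterior homeobox gene, at 2.67 ± 0.383 in brown and 45.7 ± 1.16 in white controls. Contractile, BMP-related and Schwann cell genes were higher in brown controls, and FGF feedback and hypoxia genes were lower. Ucp1 (log2 0.05, limma adjusted p = 0.787), Pparg (0.05, adjusted p = 0.753), Prdm16 (-0.15, adjusted p = 0.125), Ppargc1a (-0.04, adjusted p = 0.92) and Dusp6 (-0.13, adjusted p = 0.25) did not pass the test. Ptgs2 was lower in brown controls (-1.16, SE 0.090, limma adjusted p = 8.27e-09), as were Spry4 (-0.40, SE 0.078, adjusted p = 0.000586) and Fgfr1 (-0.34, SE 0.030, adjusted p = 5.66e-08).

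Limma called 5167 of 15222 genes different between the control depots, 2748 higher and 2419 lower in brown, and 511 of these differed at least 2-fold. Without brown control 15, 5271 were called. Of 13 brown fat lineage genes 7 were higher and 2 lower in brown controls, the same adjusted over the list alone (camera adjusted p = 0.000378, and adjusted p = 0.0138 with an estimated correlation). Zic1 was 52.6-fold, Lhx8, a homeobox gene of brown fat, 2.05-fold and Meox2, a mesodermal homeobox gene, 1.83-fold higher, while Tbx15, a transcription factor of fat depots, was slightly lower (-0.17, SE 0.037, limma adjusted p = 0.00169). White and posterior patterning genes went both ways, 7 lower and 5 higher of 16, 7 and 8 adjusted over the list alone, with a median of 0.10, a mean of -0.83 and a downward test (camera adjusted p = 0.169). Hoxa10 was 28.0-fold and Hoxa9 13.7-fold lower in brown controls.

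Of 29 FGF and ERK genes 17 were lower and 3 higher in brown controls, 18 and 3 adjusted over the list alone (camera adjusted p = 3.11e-07, and adjusted p = 0.0138 with an estimated correlation), with Spry2, another feedback inhibitor, at 18.9 ± 0.503 against 41.8 ± 0.949 RPKM in white controls and Egr2 1.96-fold lower. Of 16 hypoxia genes 11 were lower and 1 higher, the same adjusted over the list alone (camera adjusted p = 2.36e-05, and adjusted p = 0.0138 with an estimated correlation), Bnip3 by 1.61-fold. Glycolysis genes were lower for 11 and higher for 1 of 21, the same adjusted over the list alone (camera adjusted p = 7.09e-05, but adjusted p = 0.0591 with an estimated correlation), Slc16a3 by 1.96-fold. Interferon genes were lower for 19 and higher for 0 of 25, 23 and 0 adjusted over the list alone (camera adjusted p = 4.7e-08, but adjusted p = 0.419 with an estimated correlation), Mx1 by 4.61-fold and Rsad2 by 2.37-fold. Smooth muscle genes were higher for 13 and lower for 1 of 17, 14 and 1 adjusted over the list alone (camera adjusted p = 4.62e-08, and adjusted p = 0.0282 with an estimated correlation), Synpo2, an actin-bundling protein, by 2.34-fold and Notch3 by 2.27-fold. BMP and TGF-beta genes were higher for 14 and lower for 6 of 21, the same adjusted over the list alone (camera adjusted p = 0.00154, and adjusted p = 0.0282 with an estimated correlation), Bmp4, a ligand that commits precursors to the fat lineage, at 5.44 ± 0.329 against 0.727 ± 0.229 RPKM. Cholesterol genes were higher for 13 and lower for 2 of 25, 14 and 2 adjusted over the list alone (camera adjusted p = 0.00253, but adjusted p = 0.231 with an estimated correlation).

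Schwann cell markers were higher in brown controls for 7 and lower for 1 of 8, the same adjusted over the list alone (camera adjusted p = 0.000134, and adjusted p = 0.0138 with an estimated correlation). S100b stood at 8.40 ± 1.26 in brown and 5.69 ± 0.464 RPKM in white controls (limma adjusted p = 0.0186). That call was lost without white control 3 (adjusted p = 0.0523) or brown control 15 (adjusted p = 0.0538). Leukocyte markers were higher for 3 and lower for 1 of 5 (camera adjusted p = 0.35). Lyz2 stood at 2.96 ± 0.819 and 1.23 ± 0.164 RPKM, and Eng, an endothelial coreceptor of TGF-beta, was 2.10-fold higher. The inflammatory list (7 higher, 8 lower of 19) and the protease list (8 higher, 9 lower of 23) were not called (camera adjusted p = 0.35 and 0.516), though Il1rl1 was 6.50-fold and Mmp3 7.81-fold lower in brown controls. Outside the lists or in lists not called, Nov, a matricellular growth regulator, stood at 376.6 ± 6.10 against 87.8 ± 1.86 RPKM, Cp, ceruloplasmin, was 5.20-fold and the collagen Col8a1 3.47-fold higher. Cdkn1c, an imprinted cell-cycle inhibitor, was 8.36-fold and Ace, angiotensin-converting enzyme, 8.03-fold lower in brown controls. Transcripts listed more than 1 time had unequal values in the inguinal libraries for 145 accessions and in the brown libraries for 0. These entries were left out, but the depots may not have been tabulated alike, which limits every level set across depots. Depot also runs with library number, so an effect of the order of preparation or sequencing, if the numbers follow it, cannot be told from depot.

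The comparison of the depots with Fgf8b asked what set brown and white cells apart under treatment. Zic1 and Hoxc10 differed here as well: Zic1 stood at 12.7 ± 0.990 in brown and 0.163 ± 0.0817 RPKM in white cells, and Hoxc10 at 2.50 ± 0.283 and 39.5 ± 0.788 RPKM. FGF feedback genes, lower in brown controls, were higher in brown cells with Fgf8b, and stress response and cholesterol genes were lower. Ucp1 was lower in brown cells (-0.46, SE 0.116, limma adjusted p = 0.00262), as were Prdm16 (-0.30, SE 0.072, adjusted p = 0.00171) and Tbx15 (-0.43, SE 0.037, adjusted p = 2.3e-08). Ptgs2 (0.41, SE 0.090, limma adjusted p = 0.000845), Spry4 (0.73, SE 0.078, adjusted p = 3.36e-07), Dusp6 (0.62, SE 0.081, adjusted p = 4.21e-06) and Ppargc1a (1.06, SE 0.238, adjusted p = 0.00112) were higher in brown cells. The difference of Ppargc1a belongs to its summed value, since its representative transcript is too low to give it alone.

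Pparg was higher by 0.29 (SE 0.092, limma adjusted p = 0.013), a call lost without brown Fgf8b 16 (adjusted p = 0.0519), and Fgfr1 did not pass the test (0.03, adjusted p = 0.458). Limma called 7858 genes, 4098 higher and 3760 lower in brown, and 656 of these differed at least 2-fold. The split was 4230 higher and 3631 lower with median-of-ratios factors and turned to 3621 and 4217 with upper-quartile factors. Without brown control 15, which shapes the shared estimate of spread, 8513 were called. Of the genes higher in brown controls and in brown cells with Fgf8b, 1467 were shared, where independent lists would share 740, and of those lower 1234, where independent lists would share 598. The depot lists too share the same fit, filter and estimate of spread, which can raise their overlap. Higher in brown controls but lower in brown cells with Fgf8b were 337 genes, and 346 went the other way. Across genes the depot differences under both treatments had a Pearson r of 0.489, and 62% of genes had the same sign.

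Of 22 stress response genes 21 were lower and 1 higher in brown cells, the same adjusted over the list alone (camera adjusted p = 6.11e-15, and adjusted p = 0.0448 with an estimated correlation), with Trib3 at 6.41 ± 0.234 against 27.3 ± 2.73 RPKM, Vldlr 3.71-fold and Chac1 3.24-fold lower. Of 25 cholesterol genes 19 were lower and 2 higher, the same adjusted over the list alone (camera adjusted p = 3.3e-06, and adjusted p = 0.0448 with an estimated correlation). Hmgcs1 was 1.58-fold lower. Of 16 hypoxia genes 14 were lower and 0 higher (camera adjusted p = 6.59e-07, and adjusted p = 0.0163 with an estimated correlation). Of 29 FGF and ERK genes 15 were higher and 5 lower, 17 and 5 adjusted over the list alone (camera adjusted p = 0.000475, and adjusted p = 0.0448 with an estimated correlation). Egr1 was 2.68-fold and Dusp4, an ERK phosphatase, 2.37-fold higher. Lineage genes were higher for 9 and lower for 2 of 13 (camera adjusted p = 0.00111, and adjusted p = 0.0276 with an estimated correlation), Lhx8 by 2.31-fold. BMP and TGF-beta genes were higher for 16 and lower for 3 of 21 (camera adjusted p = 0.00189, and adjusted p = 0.0448 with an estimated correlation), Bmp4 by 3.77-fold at few reads.

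Lists called in camera only with the preset correlation were the patterning genes (9 lower, 4 higher of 16; adjusted p = 0.0135, but adjusted p = 0.069 with an estimated correlation), with Hoxa10 19.4-fold lower, and the matrix genes (21 lower, 12 higher of 35; 0.0125, but adjusted p = 0.57 with an estimated correlation). Lum stood at 4.70 ± 0.776 in brown and 74.7 ± 3.79 RPKM in white cells, Dcn, decorin, at 74.5 ± 7.48 and 355.2 ± 13.4 RPKM, and Col14a1 was 4.14-fold higher in brown cells. The same held for the glycolysis genes (11 lower, 2 higher of 21; 0.0135, but adjusted p = 0.261 with an estimated correlation), with Aldoc, an aldolase, 4.30-fold lower, the inflammatory genes (11 higher, 1 lower of 19, 12 and 3 adjusted over the list alone; 0.00252, but adjusted p = 0.0585 with an estimated correlation) and the interferon genes (11 higher, 0 lower of 25; 0.0034, but adjusted p = 0.7 with an estimated correlation). Thermogenic genes were not called (6 higher, 9 lower of 20; camera adjusted p = 0.611), with Cox7a1 2.48-fold lower. Among the genes with the largest differences, Agtr2, an angiotensin receptor, stood at 7.20 ± 0.676 in brown and 99.2 ± 4.05 RPKM in white cells, Esm1, a proteoglycan of activated endothelium, at 55.0 ± 2.02 and 7.93 ± 0.200 RPKM, and Cp was 5.21-fold higher in brown cells.

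**Figure D4:**
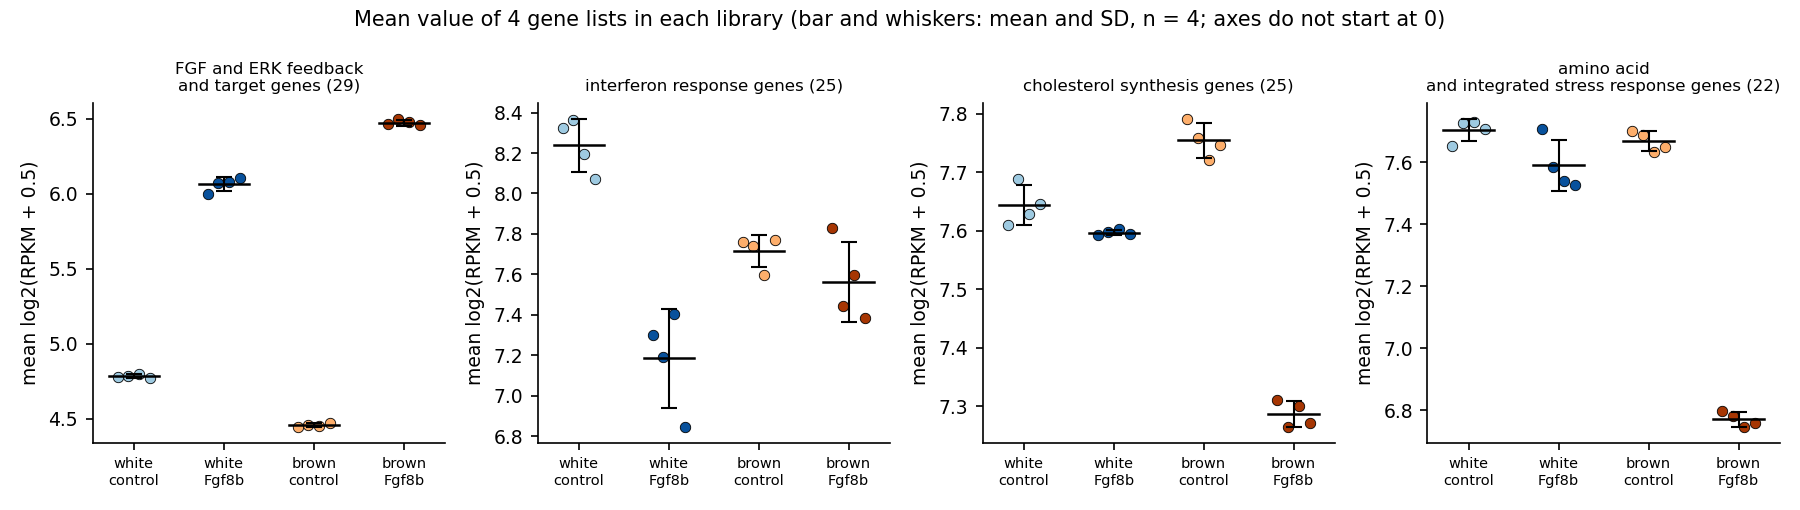
Mean log2(summed RPKM + 0.5) over the members of 4 gene lists (y axes, which do not start at 0; members in brackets) in each of the 16 libraries, by group (x axes); points are libraries, bars and whiskers are means and SD of 4 libraries. FGF and ERK genes were higher with Fgf8b in both depots, interferon genes were lower in white libraries with Fgf8b than in every white control, and cholesterol and stress response genes were lowest in brown libraries with Fgf8b.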

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

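The regroupings of libraries and the first 2 interferon tests were chosen before they were run, the latter for a fall of the list that they already named. The tests on brown control 15, on ribosomal protein genes and on leukocyte markers were chosen after the result was seen.

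With the 8 libraries of a comparison split in 35 ways into groups of 4, 1 split, the real one, called as many genes as were seen in each comparison. The real and the highest other counts were 10007 and 0 for Fgf8b in white, 10864 and 0 in brown, 5167 and 1 between control depots, and 7858 and 0 between depots with Fgf8b. Every other split mixed the real groups, which put their differences into the spread within groups and lowered its count. The counts of the other splits are therefore no chance rate, and they cannot tell how many genes chance would call. For the difference of the responses, 3 of 100 relabellings within depots, the real one included, called as many genes as the real 5313. The higher ones called 11548 and 8198 genes, and the next below called 1842. A candidate explanation for those 2 is that relabellings that swap most treatments within 1 depot test the sum of the responses. Other relabellings put the Fgf8b responses into the spread within groups, which lowers their counts. The count of 3 of 100 is therefore no chance rate, and this test cannot tell whether chance explains the difference of the responses.

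Brown control 15 stood apart from the other brown controls, with 344 of the 11790 genes with a mean of at least 5 RPKM deviating by at least 0.5 (log2) and an SD of deviations of 0.224, against 46 to 133 genes and 0.112 to 0.148 in other libraries. Its deviation followed GC content across genes (Spearman rho -0.699), computed for 10659 of these genes (90.4%). The other brown controls had a rho of 0.393 to 0.441, but each was set against a mean that includes brown control 15. Outside the brown controls the largest in size was -0.309, in brown Fgf8b 16. A difference in library preparation or sequencing may underlie the deviation of brown control 15. Genes that share most of their sequence deviated by -0.054 more than genes that share none, which argued against reads shared with near-identical copies. It correlated with the other brown controls 0.0149 better than with another group, which argued against a mislabelled sample.

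The fall of the interferon list in white preadipocytes did not rest on a single library, since at least 24 of 25 members were called lower without any 1 of the 16 libraries. The lowest control lay 0.666 above the highest Fgf8b library in the mean log2 value of the list, against a larger SD within a group of 0.244, which argued against spread between libraries. The members of the list moved together (estimated correlation 0.784), and with that correlation the camera call was lost (adjusted p = 0.289). The mean difference was -1.05 in white (exact permutation p = 0.0286, the smallest that 4 against 4 can give) and -0.15 in brown (exact permutation p = 0.2286). Whether fewer leukocytes with Fgf8b may contribute could not be told: 5 of 16 markers passed the filter, with a median of -0.43 against -0.85 for the interferon list. That test was redefined as a median over markers after a single marker had been seen, and summed Lyz2 went from 3.78 to 0.261 RPKM while Cd68 rose by 0.67 and Csf1r fell by 0.73.

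The 79 ribosomal protein genes were listed at 0 to 5096.57 RPKM, 17 under 10 and 17 over 1000, with a Spearman rho of -0.324 between shared sequence and level (permutation p = 0.0038), too weak to tell whether reads shared with near-identical copies are the cause. The lowest was Rpl10l, with 23.4% of its words shared, and Rpl3l, with 0% shared, stood at 0.09 RPKM. Such low genes with little sharing were kept in the rho and pull it toward 0. Gapdh shared 84.1% of its words and was listed at 7.76 RPKM, Pgk1 68.3% at 45.7 RPKM and Eno1 77.2% at 793.0 RPKM.

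Of 372 groups of 4 values looked at, 23 held a library apart from its group, where chance gives about 5%, and 5 of these were in brown control 15. Apart in RPKM were Hmga2 in brown Fgf8b 10 (130.3, others 134.9 to 135.6), Etv4 in brown Fgf8b 12 (27.76, others 25.56 to 25.6), Slc16a3 in white Fgf8b 2 (143.8, others 152.7 to 153.9), Pdk1 in white Fgf8b 4 (33.75, others 31.35 to 31.74), F3 in white control 1 (519.2, others 500 to 503), F3 in brown control 15 (628.4, others 552.2 to 554.7), Ube2c in white control 7 (51.09, others 47.93 to 48.45) and Il33 in white Fgf8b 2 (20.13, others 24.94 to 25.84). Apart as well were Il1rn in white Fgf8b 4 (1.022, others 0.7147 to 0.7425), Id4 in brown Fgf8b 14 (1.568, others 1.242 to 1.279), Grem1 in white Fgf8b 2 (122.7, others 148.4 to 150.8), Bnc1 in brown Fgf8b 14 (4.114, others 3.314 to 3.39), Il1rl1 in brown control 13 (7.104, others 6.908 to 6.941), Lmod1 in brown Fgf8b 12 (2.526, others 2.085 to 2.124), Aspn in brown control 15 (61.79, others 42.47 to 42.7) and Vldlr in brown control 15 (8.518, others 7.276 to 7.478). The remaining ones were Vldlr in brown Fgf8b 10 (1.824, others 2.094 to 2.139), Hoxc10 in white Fgf8b 6 (40.7, others 39.07 to 39.23), Hoxa10 in white control 7 (15.5, others 16.95 to 17.12), Col8a1 in brown control 15 (95.14, others 90.65 to 91.07), Cp in brown control 15 (15.62, others 12.52 to 12.55) and Dusp4 in white Fgf8b 2 (26.65, others 30.47 to 30.87). Brown control 9 had 13.7 M reads, the other brown controls 15.8 to 16.1 M.

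Of 71 genes looked at, 58 had an Fgf8b response that differed between depots in limma's interaction test (log2, brown minus white), against 5313 of all 15222 genes (34.9%). Some of the 71 were named for a large difference in this same test, which raises their share. Responses were higher in brown for Il1rl1 2.85, Angptl4 2.79, Mx1 2.57, Col14a1 2.46, Egr1 1.96, Rsad2 1.96, Dusp5 1.94, Egr2 1.82, Il11 1.69, Klf15 1.64, Igfbp3 1.62 and Ptgs2 1.58. Smaller values in that direction were Ifit3 1.54, Il1rn 1.51, Mmp3 1.28, Ltbp1 1.26, Lpl 1.23, Spry4 1.13, Ppargc1a 1.10, Fgfr2 1.04, Usp18 0.93, Areg 0.78, Dusp6 0.74 and Etv4 0.72. The smallest were Spp1 0.70, F3 0.69, Sema7a 0.69, Ptges 0.65, Fmod 0.46, Hmga2 0.45, Rrm2 0.40, Fgfr1 0.37, Pfkl 0.26 and Timp3 0.12. Responses were lower in brown for Rgs5 -2.97, Lum -2.92, Serpinb1a -2.32, Il33 -2.29, Aspn -2.04, Eln -1.94, Chac1 -1.94, Tgfb2 -1.79, Trib3 -1.70, Vldlr -1.59, Notch3 -1.54 and S100b -0.90. Smaller values in that direction were Lmod1 -0.90, Wisp2 -0.90, Cnn1 -0.85, Bnc1 -0.79, Hmgcs1 -0.76, Col12a1 -0.70, Acot2 -0.62, Tm7sf2 -0.56, Adamts5 -0.55, Ucp1 -0.51, Ccnb2 -0.26 and Ptgs1 -0.23.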

How the results depend on the processing

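Of 178 results for named genes, 9 were altered in at least 1 alternative. Of 4796 pairs of a result and an alternative, 4783 gave the same call and direction, 4 lost a call and 9 turned a direction. The cause was not tested. The alternative thresholds (adjusted p under 0.01, 2-fold, treat against 1.5-fold) were applied to counts only, so named results that they would drop are not among these. Scaling by library size only, counted as an alternative, is the main fit itself. Leaving out a library of a group not compared changed only the filter and the shared estimate of spread. Many of the genes were named for a large change in these data. The agreement of the 4783 pairs was therefore partly fixed in advance. The directions that turned belonged to differences that had not passed limma's test. Fgfr1 in white preadipocytes turned to -0.028 with median-of-ratios and -0.039 with upper-quartile factors (adjusted p 0.261 to 0.805 over its alternatives), and Fgfr1 between depots with Fgf8b to -0.002 with upper-quartile factors (0.302 to 0.966). Between control depots, with each library left out in turn, Ucp1 ran from -0.044 without brown control 11 to 0.149, Pparg from -0.001 without brown control 9 to 0.068, and Ppargc1a from -0.22 to 0.11. Ppargc1a turned without white control 3 (0.10), brown control 13 (0.11) or brown control 15 (0.04). Prdm16 between control depots was 0.002 on its most abundant transcript.

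S100b between control depots lost its call without white control 3 (0.50, limma adjusted p = 0.0523) or brown control 15 (0.46, adjusted p = 0.0538; 0.0019 to 0.0538 over its alternatives). Lyz2 there lost its call with a pseudocount of 0.1 (1.23, limma adjusted p = 0.084; 0.000147 to 0.084). Pparg between depots with Fgf8b lost its call without brown Fgf8b 16 (0.23, limma adjusted p = 0.0519; 0.00179 to 0.0519).

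Voom on recovered reads tested 7939 genes, against 15222 in the main test, so its lower counts do not show a weaker result. It called 5388 for Fgf8b in white, 5654 in brown, 2781 between control depots, 4102 between depots with Fgf8b and 2683 for the difference of the responses. Of these, 5155, 5460, 2450, 3813 and 2404 were called in the same direction in the main test. In the same order, a fold change of at least 2 left 1779, 2177, 511, 656 and 604 genes, and treat against 1.5-fold left 2282, 2928, 497, 683 and 358. At an adjusted p under 0.01 the difference of the responses held 3538 genes in limma. With each library left out the counts ran from 9478 to 10389, 10428 to 10872, 4479 to 5271, 7199 to 8513 and 4839 to 5875. A block of adjacent library numbers gave 10105 genes for Fgf8b in white, 10981 in brown and 5538 for the difference of the responses.

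The correlation of the responses was 0.844 without a filter, 0.862 with a stricter filter, 0.872 on RefSeq transcripts, 0.799 as Spearman's rho, 0.862 for genes called in either depot, and 0.851 to 0.858 with each library left out. With an estimated correlation camera called 3 lists for Fgf8b in white, 2 in brown, 6 between control depots, 6 between depots with Fgf8b and 4 for the difference of the responses, and fry called 22, 25, 18, 22 and 15.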

Other observations

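Lists not called between the control depots are given here as values, higher and lower in brown, with camera's adjusted p. They were 3 and 6 of 20 thermogenic genes (0.856; 5 and 6 adjusted over the list alone), 5 and 4 of 22 differentiation genes (0.751; 5 and 5), 13 and 6 of 24 preadipocyte markers (0.377; 13 and 7), 3 and 3 of 9 FGF receptors (0.989; 5 and 3), 4 and 6 of 17 prostaglandin genes (0.301), 3 and 5 of 36 respiratory chain genes (0.856; 1 and 1) and 0 and 0 of 6 mitochondrially encoded genes (0.856). They were 8 and 6 of 35 proliferation genes (0.856; 8 and 7), 8 and 15 of 35 matrix genes (0.392), 3 and 9 of 22 stress response genes (0.29; 4 and 10), 6 and 6 of 16 WNT genes (0.856; 7 and 6), 4 and 4 of 9 endothelial (0.799; 5 and 4), 2 and 0 of 7 skeletal muscle (0.5; 3 and 0), 1 and 0 of 6 epithelial (0.989; 0 and 0) and 2 and 0 of 6 mesothelial markers (0.29).

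Lists not called between depots with Fgf8b were 7 and 4 of 22 differentiation genes (0.671), 9 and 10 of 24 preadipocyte markers (0.616; 9 and 11 adjusted over the list alone), 2 and 2 of 9 FGF receptors (0.911; 1 and 2), 9 and 4 of 17 prostaglandin genes (0.514), 7 and 2 of 36 respiratory chain genes (0.616; 6 and 1; 6 and 6 with upper-quartile factors) and 0 and 1 of 6 mitochondrially encoded genes (0.616). They were 18 and 5 of 35 proliferation genes (0.0914), 10 and 9 of 23 protease genes (0.817), 7 and 3 of 17 smooth muscle genes (0.0914; 8 and 3), 4 and 4 of 16 WNT genes (0.72), 1 and 1 of 5 leukocyte (0.616), 5 and 3 of 9 endothelial (0.563), 0 and 5 of 7 skeletal muscle (0.0914), 1 and 1 of 6 epithelial (0.784), 5 and 2 of 8 Schwann cell (0.163; 5 and 3) and 4 and 1 of 6 mesothelial markers (0.163; 4 and 2).

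Between groups of 4, complete separation without overlap of values occurred for 9609 genes (63.1%) in white and 9351 (61.4%) in brown preadipocytes with Fgf8b, 4794 (31.5%) between control depots and 7486 (49.2%) between depots with Fgf8b, where chance gives 2.9%.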
